A study of Mus musculus with 6 samples.

How the data were processed

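Gene expression was measured by RNA sequencing of total RNA from mouse quadriceps, with 3 libraries of the Cre-only control (MyoCre) and 3 of the muscle Klf15 knockout (K15SKO), all at 2 months of age. Per the labels' protocols, RNA was isolated with a Roche column kit and made into libraries by Illumina methods; strandedness is not given in the sources used here. Per the submitters' processing notes, STAR, Cufflinks, Cuffdiff and the mm10 build were used, and their versions are not given in the sources used here. The authors deposited a matrix of FPKM, a level scaled by transcript length and by the mapped fragments of the library, for 23314 genes in the 6 libraries. The unit is read from those tools and from the values, since the matrix does not name it. FPKM corrects for gene length and library size but keeps no counts, so a gene with few reads and a gene with many cannot be weighted by their counting error.

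Columns were matched to samples by the sample descriptions, and 0 columns belonged to no sample. Gene coordinates and classes came from GENCODE M21 on GRCm38, which is the mm10 assembly: 18068 IDs matched with their version and 23193 without it. There were 32 symbols on more than 1 row, 0 rows at 0 in every library and 2 rows of mitochondrial genes. Acta1, Ckm, Myh4, Aldoa, Atp2a1, Tnnt3 and Tpm1 were not analysed here. A value of exactly 0 can be a failed estimate in FPKM tables or an unexpressed gene. In all, 102 tested genes were at 0 in every library of a group, 34 of them above 0 in every library of the other. Most of the 34 were high in K15SKO 2 alone and passed the filter only through it. The liver gene Cps1, for example, was at 0.708, 58.6 and 0.0555 FPKM in K15SKO 1 to 3. Reads of overlapping or antisense genes such as Myh1 and Gm12300 may have been split by the authors' counting and their values are uncertain.

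Depth was read from values under 0.1 FPKM, which fall in steps of what 1 read is worth. The most common log2 ratio of these values against MyoCre 1 was −0.11 and −0.40 in MyoCre 2 and 3, and 0.41, −0.65 and 0.16 in K15SKO 1 to 3. Relative depth is the inverse of that ratio. The absolute depth is unknown, so no counting interval is given.

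Genes with a mean over the 6 libraries of at least 1 FPKM (11607) were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. A log2 difference on this scale understates the change of low genes. Klf15 was also tested with an exact two-sided permutation test, for which 3 against 3 libraries give 0.1 at the smallest. Of 33 gene lists, 31 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The lymphocyte and neutrophil list had 0 tested members and the sex-linked list 4. Tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots with matplotlib 3.10.9.

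The groups, the test, the lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names Klf15; up to 12 genes per direction that passed the threshold with no overlap between the groups, filled by the smallest unadjusted p; up to 4 members per list with the smallest p; and 16 genes of earlier work on Klf15 or muscle lipid use. Genes with names of the forms Gm with digits, Rik, -ps, Mir or Snor were left out of the ranked part, where 2 were counted only. The alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-of-ratios and quantile scaling, eBayes without trend or robust, array weights, the replicate number as a block, and each library left out in turn. Added after seeing the data were the fits without genes at 0 in a whole group, with protein-coding genes alone, and with each K15SKO library alone, where the spread comes from MyoCre alone. A list of 40 liver genes was also chosen after seeing the data.

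The scripts were tested on simulated data for the K15SKO and MyoCre comparison over 11607 genes. With the spread of all libraries, 65% of 100 genes changed by a log2 of 1 and 93% of 100 changed by 2 were recovered, with 6 false calls. With the spread of the MyoCre libraries the shares were 81% and 98%, with 4 false calls. The changed genes were drawn from those with a mean log2 value above 1 in MyoCre and not at 0 in a whole group. Both simulated groups had the same spread, whereas the real median SD was 0.115 in MyoCre and 0.224 in K15SKO. The shares are therefore not the power of the real test. A shifted list of 41 members was found with 0 other lists called, but genes were drawn independently with the MyoCre spread. Members of real lists vary together, with an estimated correlation of 0.887 for macrophage markers. The simulation therefore cannot show how often camera calls lists falsely in these data.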

Results

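RNA sequencing measured transcript levels in the quadriceps, the large muscle at the front of the thigh, of 2-month-old mice of 2 genotypes. MyoCre mice carried 1 copy of Cre recombinase driven by Myogenin, a gene switched on in differentiating muscle, and served as the control. K15SKO mice carried the same Cre together with floxed Klf15, so that Klf15 is deleted in muscle. Each group held 3 libraries, numbered 1 to 3 from the labels; the design text speaks of n = 4, and no further libraries were analysed here. Values are FPKM for 23314 genes. Their sums were 399372, 397426 and 423214 in MyoCre 1 to 3 and 401505, 396375 and 466756 in K15SKO 1 to 3, which is not a depth, since read totals were not used here. From the steps between low values, the depth relative to MyoCre 1 was 1.08 and 1.32 in MyoCre 2 and 3, and 0.75, 1.57 and 0.90 in K15SKO 1 to 3. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these samples.

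The comparison of K15SKO with MyoCre asks which quadriceps transcripts differ when Klf15 is deleted in muscle. Klf15 was lower in 3 of 3 K15SKO libraries, at 9.76 ± 10.5 FPKM against 31.4 ± 3.47 FPKM in MyoCre (SD, n = 3 each). Genes of slow muscle fibres and of denervated or regenerating muscle stood higher in K15SKO as groups, and adipocyte markers and genes of branched-chain amino acid catabolism stood lower. These calls rest on camera's preset correlation: each had an adjusted p of 0.698 with an estimated correlation. Igfn1 and Npc1 fell to 1.83 ± 0.315 and 7.43 ± 1.40 FPKM, from 13.7 ± 2.98 and 30.5 ± 5.14 FPKM (SD, n = 3 each), calls that held in 11 and 8 of 18 alternatives. The K15SKO libraries differed among themselves. Macrophage and regeneration genes were high in K15SKO 1 and 2 and near the MyoCre level in K15SKO 3. The median of slow fibre genes was high in K15SKO 1 and 3 and within the range of the MyoCre libraries in K15SKO 2. Liver transcripts were high in K15SKO 2 and low, but for most genes above MyoCre, in K15SKO 1 and 3.

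Klf15 encodes a zinc-finger transcription factor and lies on chromosome 6 from 90462576 to 90475238 on the plus strand of GRCm38. It was listed at 35.2, 28.4 and 30.5 FPKM in MyoCre 1 to 3 and at 2.22, 21.7 and 5.32 FPKM in K15SKO 1 to 3. These K15SKO values are 7.08%, 69.3% and 17.0% of the MyoCre mean. The log2 change on the log2(FPKM + 1) scale was −2.06 (SE 0.66), with a limma adjusted p of 0.273. The exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. An FPKM covers the whole gene, and the deleted part is not given in the sources used here. Alb, the albumin transcript of liver, stood at 1.13, 0.298 and 0.311 FPKM in MyoCre 1 to 3 and at 21.1, 2203 and 4.36 FPKM in K15SKO 1 to 3.

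**Figure D1:**
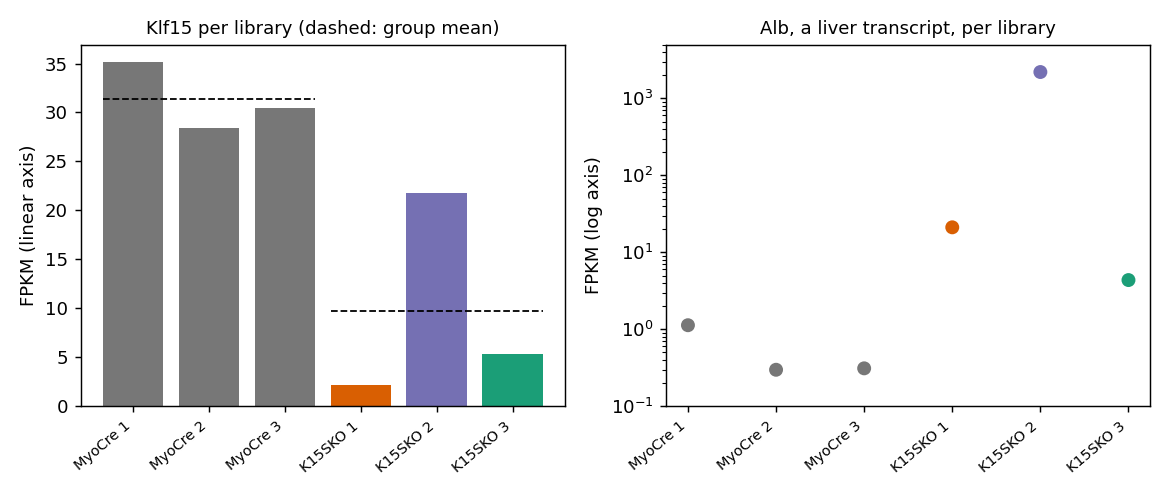
FPKM of Klf15 (left, linear axis, bars per library with the group mean dashed) and of Alb (right, log axis, points) in 3 MyoCre and 3 K15SKO libraries. Klf15 lies below the MyoCre libraries in all 3 K15SKO libraries and is highest among them, at 21.7 FPKM, in K15SKO 2, where Alb reaches 2203 FPKM.

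Of 11607 genes tested with limma, 6 passed an adjusted p of 0.05, with 2 higher and 4 lower in K15SKO. Igfn1, a protein of the sarcomere with immunoglobulin and fibronectin domains, fell by 2.37 on the log2 scale (SE 0.18, limma adjusted p = 0.0145) and was lower in 3 of 3 K15SKO libraries. Npc1, which moves cholesterol out of late endosomes and lysosomes, fell by 1.90 (SE 0.17, limma adjusted p = 0.0389), also in 3 of 3 libraries. The other 4 genes were listed at exactly 0 in every library of a group, which can be a failed estimate or an unexpressed gene. Pvalb, the calcium buffer of fast fibres, was listed at 0 in MyoCre 1 to 3 and at 5041, 6810 and 15958 FPKM in K15SKO 1 to 3. Myh1, the myosin heavy chain of type IIx fibres, was listed at 486, 350 and 505 FPKM in MyoCre and at 0 in K15SKO. Gm12300, an antisense gene that overlaps Myh1, stood at 56.2, 55.4 and 55.6 FPKM in MyoCre and at 0 in K15SKO. Gm25994, a microRNA gene, was at 0 in MyoCre and at 121, 31.0 and 61.3 FPKM in K15SKO; the last 2 genes fall outside the rule for named genes and were chosen after their values were seen. Pvalb lies on chromosome 15 from 78191114 to 78206400, Myh1 on chromosome 11 from 67200052 to 67224575 on the plus strand, and Gm12300 from 67211256 to 67237573 on the minus strand.

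With the genes listed at 0 in a whole group left out, a choice made after seeing the data, limma called 0 genes, against 1930 at an unadjusted p under 0.05. Igfn1 and Npc1 then had adjusted p of 0.0609 and 0.103, within ranges of 0.00518 to 0.225 and 0.00893 to 0.337 over 18 alternatives. Neither gene passed without MyoCre 1, MyoCre 2, K15SKO 1 or K15SKO 2 (0.132, 0.158, 0.144 and 0.0743 for Igfn1), with no filter (0.077) or with the replicate block (0.225). Npc1 also did not pass without MyoCre 3 (0.104), with median-of-ratios rescaling (0.0795) or with eBayes without trend (0.0565). Among all 11607 genes, 1920 had an unadjusted p under 0.05, 978 higher and 942 lower. Independent unchanged genes would give 580, and other splits of the 6 libraries gave 59 to 1536. The 3 values of each group did not overlap for 2867 genes, 24.7% where chance gives 10%. Without K15SKO 3, which the labels give no ground to leave out, the count of changed genes was 2743. It was 3 without MyoCre 1 and 3 without MyoCre 2. Over the genes tested, log2 values of K15SKO 3 correlated (Pearson) at 0.975, 0.968 and 0.97 with MyoCre 1 to 3. They correlated at 0.942 and 0.88 with K15SKO 1 and 2, so K15SKO 3 lay closer to MyoCre than to its own group.

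The genes that came next by unadjusted p, with no overlap between the groups, did not pass the test. Among the 11 listed for higher values, limma adjusted p ran from 0.153 to 0.228, and log2 differences from 0.62 to 2.56. They included Actn2, the alpha-actinin of the Z disc, at 536 ± 105 against 178 ± 31.6 FPKM, and Myom3, an M-band protein, at 24.9 ± 11.9 against 3.88 ± 0.768 FPKM (SD, n = 3 each). Otud1, a deubiquitinase, stood at 40.6 ± 11.3 against 10.2 ± 2.39 FPKM, and Smtnl1 at 67.1 ± 23.0 against 19.2 ± 2.77 FPKM. The others were Casq2, Adprhl1, Sh3rf2, Tmem25, Cox18, Pdss1 and Tmbim4. Among the 9 listed for lower values, adjusted p ran from 0.0538 to 0.228. Casp12, a caspase of the endoplasmic reticulum, stood at 6.12 ± 0.276 against 12.2 ± 0.540 FPKM. Cish, a suppressor of cytokine signalling, was at 6.44, 2.62 and 3.23 FPKM in K15SKO 1 to 3 against 37.5, 32.8 and 99.3 FPKM in MyoCre. Mettl21c, a muscle lysine methyltransferase, stood at 28.7 ± 9.91 against 97.0 ± 11.5 FPKM, and Pdp2, a pyruvate dehydrogenase phosphatase, at 0.795 ± 0.339 against 4.05 ± 1.07 FPKM. The rest were BC023105, a processed pseudogene, and Tpx2, Neto2, Adipoq and Htra4.

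**Figure D2:**
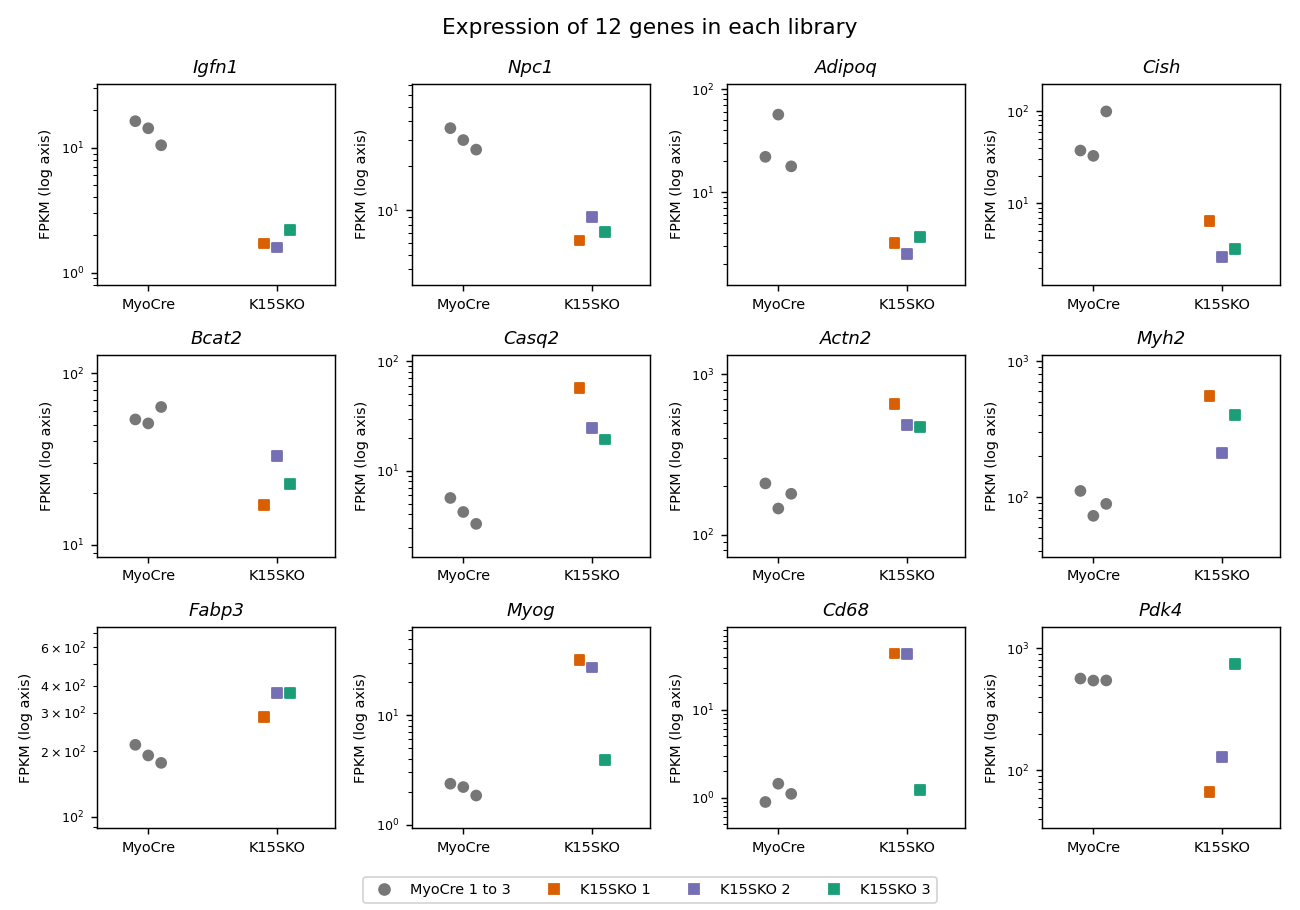
FPKM (log axis) of 12 genes in each library, with MyoCre as circles and K15SKO as squares coloured by library. Igfn1, Npc1, Adipoq, Cish and Bcat2 lie lower and Casq2, Actn2, Myh2 and Fabp3 higher in all 3 K15SKO libraries, while Cd68 (43.8, 43.6 and 1.24 FPKM) and Pdk4 (67.0, 129 and 749 FPKM) differ between K15SKO libraries.

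Gene lists were tested with limma's camera, and 14 of 31 passed an adjusted p of 0.05, 7 higher and 7 lower. None of the 14 passed with an estimated correlation, where adjusted p ran from 0.698 to 0.746, or with fry, where it ran from 0.204 to 0.562. No list member other than Pvalb and Myh1 passed over all genes tested.

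Genes of branched-chain amino acid catabolism fell as a list, with a median log2 difference of −0.42 (camera adjusted p = 8.37e-05, and adjusted p = 0.698 with an estimated correlation). Of 24 members, 13 were lower at an unadjusted p under 0.05 and 0 higher, 5 were lower adjusted over the list alone, and 0 passed over all genes. Bcat2, the transaminase that starts the pathway, stood at 24.1 ± 8.10 against 56.0 ± 6.59 FPKM (SD, n = 3 each, limma adjusted p = 0.248), lower in 3 of 3 libraries. Ivd, isovaleryl-CoA dehydrogenase, was at 28.5 ± 7.98 against 51.8 ± 5.12 FPKM, Bckdha at 69.1 ± 18.3 against 117 ± 11 FPKM and Pcca at 16.5 ± 4.06 against 27.3 ± 1.51 FPKM. The list's median stood 0.70, 0.27 and 0.24 log2 units below the MyoCre mean in K15SKO 1 to 3.

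Adipocyte markers fell as a list, with a median of −1.93 (camera adjusted p = 9.12e-10, and adjusted p = 0.698 with an estimated correlation). Of 14 members 11 were lower adjusted over the list alone. The fat hormone genes Adipoq and Cfd stood at 3.11 ± 0.578 against 32.1 ± 21.3 FPKM and at 30.5 ± 11.5 against 196 ± 112 FPKM, and the lipid droplet genes Cidec and Plin1 at 1.63 ± 0.665 against 25.3 ± 18.2 FPKM and 0.945 ± 0.181 against 15 ± 10.6 FPKM (SD, n = 3 each). The MyoCre libraries spread widely here, with Adipoq at 22.0, 56.6 and 17.8 FPKM. The lipid lists share fat genes: Lipe, hormone-sensitive lipase, stood at 7.57 ± 2.99 against 24.6 ± 9.79 FPKM, Fabp4 at 138 ± 56.7 against 391 ± 174 FPKM and Fasn, fatty acid synthase, at 4.93 ± 2.45 against 40.3 ± 25.4 FPKM.

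The lists of muscle lipid use did not pass: camera adjusted p was 0.534 for fatty acid uptake and activation, 0.135 for the carnitine shuttle and beta-oxidation, 0.0755 for triglyceride storage and lipolysis, 0.0876 for PPAR target genes and 0.249 for sterol and fatty acid synthesis. Fabp3, the muscle fatty acid binding protein, stood at 343 ± 48.5 against 194 ± 18.8 FPKM, higher in 3 of 3 libraries (SD, n = 3 each, limma adjusted p = 0.248). Cpt1b, which admits fatty acids to mitochondria, was at 104, 107 and 205 FPKM in K15SKO 1 to 3 against 156 ± 4.73 FPKM in MyoCre. Slc25a20 stood at 46.5 ± 10.5 against 51.6 ± 4.13 FPKM, Acsl1 at 109 ± 24.1 against 124 ± 18.2 FPKM and the fatty acid transporter gene Cd36 at 90.4 ± 55.9 against 114 ± 27.2 FPKM. Slc27a1 was at 13.3, 15.6 and 37.4 FPKM against 36.7 ± 3.48 FPKM, and Ucp3 at 18.4, 39.2 and 124 FPKM against 173 ± 48.5 FPKM. Pdk4, which restrains glucose oxidation, was at 67.0, 129 and 749 FPKM against 553 ± 11.9 FPKM. Angptl4 and Ppard had log2 differences of −0.66 and −0.30 (limma adjusted p = 0.314 and 0.330). Without K15SKO 3 the camera adjusted p was 0.000249 for beta-oxidation (median −0.34), 0.00124 for PPAR targets (−0.47) and 0.025 for triglyceride storage (−0.34). Without MyoCre 3 it was 0.00129 for triglyceride storage, 0.0209 for PPAR targets and 0.0146 for sterol and fatty acid synthesis. Without K15SKO 2 it was 0.0273 for PPAR targets and 0.0025 for sterol and fatty acid synthesis. The adipocyte marker medians against the MyoCre mean were 0.0592, 0.8255 and −0.675 in MyoCre 1 to 3. Leaving out MyoCre 3 thus raises the fat transcripts of the control mean, so the passes without it need not come from muscle fibres. How much fat transcripts added to those passes was not tested.

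Glucose uptake, glycolysis and glycogen genes fell as a list of 30 (median −0.25, camera adjusted p = 0.0109, and adjusted p = 0.722 with an estimated correlation). Its medians were −0.47, −0.47 and 0.12 in K15SKO 1 to 3 against the MyoCre mean. No member passed adjusted over the list alone. Pfkfb3, which sets the level of a glycolytic activator, was at 55.3 ± 26.0 against 118 ± 24.5 FPKM, and Slc2a4, the insulin-responsive glucose transporter, at 269 ± 50.1 against 351 ± 20.1 FPKM (limma adjusted p = 0.295). Gbe1, the glycogen branching enzyme, went the other way at 43.3 ± 13.3 against 22.8 ± 1.88 FPKM. This list did not pass without K15SKO 1 (0.0657) or without K15SKO 2 (0.0669). Tricarboxylic acid cycle genes did not pass (median −0.17, camera adjusted p = 0.609), but passed without K15SKO 3 (0.00203) and with array weights (0.0194). Oxidative phosphorylation subunits had a median of 0.01 (camera adjusted p = 0.534); the median was −0.07 after quantile normalization, 0.18 without K15SKO 2 (0.00124) and −0.16 without K15SKO 3 (0.0225). Cox6a2, a muscle subunit of cytochrome c oxidase, stood at 800 ± 48.9 against 1311 ± 74.8 FPKM and was the single member lower adjusted over the list alone.

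Regulators of mitochondrial and lipid genes fell as a list of 25 (median −0.36, camera adjusted p = 0.000542, and adjusted p = 0.698 with an estimated correlation). The list's medians were −0.46, −0.55 and 0.02 in K15SKO 1 to 3 against the MyoCre mean. Nrip1, a nuclear receptor corepressor, stood at 5.04 ± 0.760 against 8.33 ± 1.24 FPKM and Ppargc1a, a coactivator of mitochondrial genes, at 8.68 ± 5.31 against 14.7 ± 5.01 FPKM (limma adjusted p = 0.366). Circadian clock genes fell as a list of 19 (median −0.28, camera adjusted p = 0.0063, and adjusted p = 0.698 with an estimated correlation), with Rora at 12.4 ± 3.62 against 24.8 ± 1.68 FPKM, the single member past the threshold adjusted over the list alone. The list's medians were −0.47, −0.21 and −0.04 in K15SKO 1 to 3. Ubiquitin ligase and autophagy genes of muscle atrophy fell as a list of 23 (median −0.25, camera adjusted p = 0.0317, and adjusted p = 0.698 with an estimated correlation). Their medians were −0.44, −0.36 and −0.04 in K15SKO 1 to 3. They did not pass without MyoCre 2 (0.0518) or without K15SKO 1 (0.108). Fbxo32, the ligase atrogin-1, was at 41.8, 38.9 and 110 FPKM against 130 ± 6.02 FPKM (limma adjusted p = 0.275). Mstn, myostatin, stood at 18.8 ± 7.14 against 37.6 ± 6.85 FPKM, and Trim63, the ligase MuRF1, at 237 ± 65.9 against 213 ± 52.0 FPKM.

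Related lists did not pass: camera adjusted p was 0.127 for Krüppel-like factors, 0.609 for glucocorticoid-responsive genes and 0.534 for other amino acid catabolism. Klf9 stood at 42.5 ± 17.0 against 71.6 ± 9.86 FPKM and Klf10 at 4.37 ± 2.18 against 10.6 ± 4.83 FPKM. Smox and Amd1, of polyamine breakdown and synthesis, stood at 141 ± 80.5 against 331 ± 29.9 FPKM and 99.5 ± 55.2 against 269 ± 66.5 FPKM. Prodh, Gpt and Errfi1 were highest in the library with the most liver transcripts, K15SKO 2, at 11.9, 35.7 and 49.7 FPKM. In K15SKO 1 and 3 Prodh was at 1.26 and 1.98 FPKM against 5.09 ± 0.810 FPKM in MyoCre, Gpt at 20.4 and 13.4 against 12.8 ± 0.544 FPKM, and Errfi1 at 14.1 and 10.8 against 6.98 ± 0.436 FPKM.

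Slow fibre genes rose as a list of 15 (median 1.68, camera adjusted p = 1.61e-06, and adjusted p = 0.698 with an estimated correlation). Adjusted over the list alone 5 were higher and 0 lower. Casq2, the slow and cardiac calsequestrin, stood at 33.5 ± 20.3 against 4.36 ± 1.19 FPKM, Myoz2 at 129 ± 45.4 against 32.8 ± 11.9 FPKM and Ankrd2 at 255 ± 32.1 against 109 ± 40.7 FPKM (SD, n = 3 each). The list median was 2.41, 0.35 and 2.16 log2 units above the MyoCre mean in K15SKO 1 to 3. The MyoCre libraries ranged from −0.76 to 0.72, so K15SKO 2 lay within their range. The groups did not overlap for 5 of the 15 members. Myh7 overlapped, at 28.6, 3.83 and 60.8 FPKM in K15SKO 1 to 3 against 7.88, 13.4 and 0.363 FPKM in MyoCre 1 to 3. Myl3 and Mb overlapped too, at 24.2 and 1245 FPKM in K15SKO 2. Fast fibre genes did not pass (median −0.43, camera adjusted p = 0.0589), and their mean of 0.11 has the other sign because Pvalb and Myh1 are listed at 0 in opposite groups. Myh2, the type IIa myosin, stood at 389 ± 171 against 91.2 ± 19.2 FPKM, and Mylk2, the myosin light chain kinase, at 236, 269 and 575 FPKM against 665 ± 80.9 FPKM. The fast list passed after median-of-ratios scaling (0.0394), with eBayes without trend (0.0486), with array weights (0.00724), without MyoCre 2 (0.0437) and without K15SKO 3 (0.00217).

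Denervation and regeneration genes rose as a list of 18 (median 1.35, camera adjusted p = 3.33e-05, and adjusted p = 0.698 with an estimated correlation). Adjusted over the list alone 8 were higher and 0 lower. The list median was 1.85 and 1.74 log2 units above the MyoCre mean in K15SKO 1 and 2 and 0.17 above it in K15SKO 3. Myog, the myogenic factor, was at 31.9, 27.3 and 3.90 FPKM against 2.13 ± 0.266 FPKM, and Chrna1, an acetylcholine receptor subunit, at 11.6, 11 and 4.27 FPKM against 2.56 ± 0.303 FPKM. Satellite cell markers rose as a list of 7 (median 0.29, camera adjusted p = 0.0316, and adjusted p = 0.698 with an estimated correlation), but not without K15SKO 2 (0.0763). Itga7 was at 66.9, 54.0 and 24.0 FPKM against 20.0 ± 1.04 FPKM.

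Macrophage markers rose as a list of 14 (median 1.08, camera adjusted p = 0.000304, and adjusted p = 0.698 with an estimated correlation), with medians of 2.19, 1.33 and −0.18 in K15SKO 1 to 3 against the MyoCre mean. Cd68, a macrophage lysosomal protein, was at 43.8, 43.6 and 1.24 FPKM against 1.15 ± 0.278 FPKM, and Lyz2 at 173, 83.6 and 18.6 FPKM against 21.3 ± 2.25 FPKM. Extracellular matrix and fibrosis genes rose as a list of 23 (median 0.60, camera adjusted p = 4.31e-05, and adjusted p = 0.698 with an estimated correlation), with medians of 1.35, 0.69 and −0.05. The osteopontin gene Spp1 was at 19.5, 13.8 and 0.895 FPKM against 0.671 ± 0.109 FPKM. Interferon response genes rose as a list of 18 (median 0.31, camera adjusted p = 0.0079, and adjusted p = 0.722 with an estimated correlation), with medians of 0.64, 0.28 and −0.13 in K15SKO 1 to 3, but not without K15SKO 1 (0.24). Immediate early and heat shock genes rose as a list of 18 (median 0.50, camera adjusted p = 8.37e-05, and adjusted p = 0.698 with an estimated correlation). The early response genes Fos and Zfp36 stood at 7.14 ± 2.01 against 2.17 ± 0.703 FPKM and 9.40 ± 1.25 against 4.80 ± 0.882 FPKM, the 2 members higher adjusted over the list alone. Endothelial markers fell as a list of 16 (median −0.27, camera adjusted p = 0.045, and adjusted p = 0.746 with an estimated correlation). Their medians were −0.67, −0.43 and 0.27 in K15SKO 1 to 3 against the MyoCre mean. They did not pass without MyoCre 1 (0.198), K15SKO 1 (0.396) or K15SKO 2 (0.0908), nor after quantile normalization (0.0698) or with protein-coding genes alone (0.0581).

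**Figure D3:**
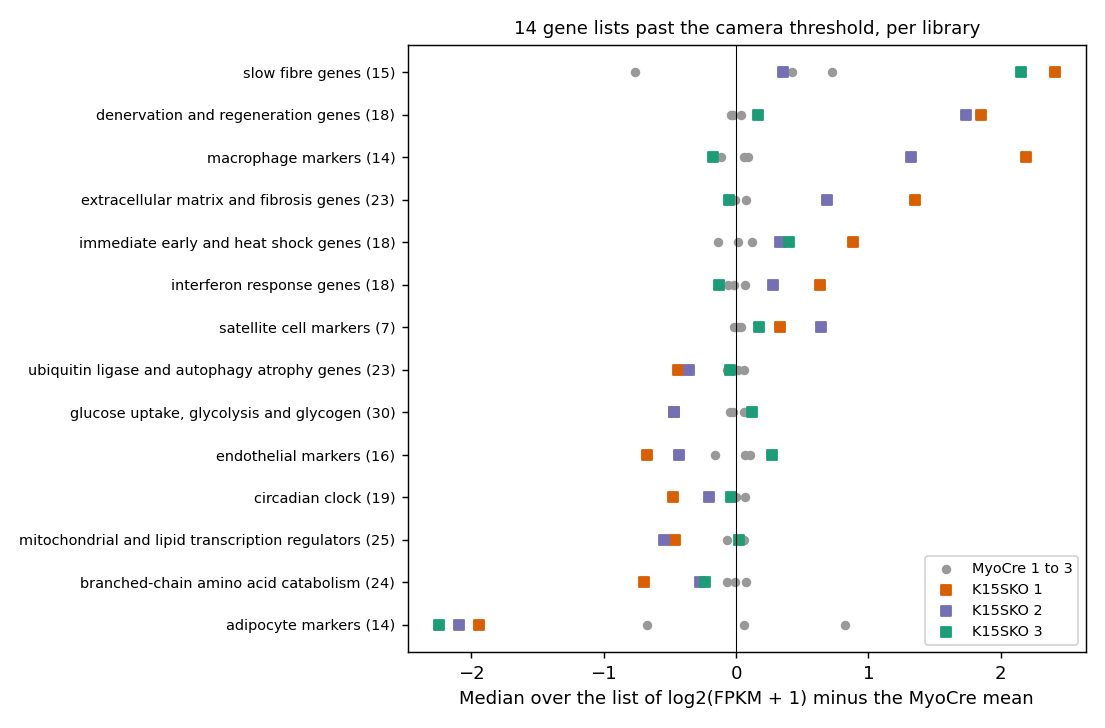
Median over each of the 14 lists past the camera threshold of log2(FPKM + 1) minus the MyoCre mean, per library, with MyoCre as circles, K15SKO as squares and the number of tested members in brackets. Adipocyte markers lie between −2.24 and −1.94 in the 3 K15SKO libraries, while denervation and regeneration genes lie at 1.85, 1.74 and 0.17.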

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

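The fits without genes at 0 in a whole group, with protein-coding genes alone and with each K15SKO library alone were chosen after seeing the data. Klf15 kept its direction and stayed short of the threshold in 18 alternatives, which leave out the fits of K15SKO libraries alone, with log2 changes from −2.84 to −1.37 and limma adjusted p from 0.0947 to 0.581. Against MyoCre, K15SKO 1 to 3 alone gave Klf15 changes of −3.32, −0.50 and −2.35. The count of 6 changed genes became 3 with no filter on low values, where more genes were tested, 0 with genes at 0 in a whole group left out (1930 at an unadjusted p under 0.05), and 2398 with array weights, which gave K15SKO 3 a weight of 0.20; for the last the cause was not tested. Leaving out 1 library gave 3 to 2743 genes, the highest without K15SKO 3. Against the 3 MyoCre libraries, K15SKO 1 alone gave 2805 genes, K15SKO 2 alone 1693 and K15SKO 3 alone 18; these fits take their spread from MyoCre alone (median SD 0.115, against 0.224 in K15SKO), so the counts support no call. Apart from the replicate block (3), the other alternatives gave counts within 1.5 times of 6.

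The 14 lists became 9 at a mean of at least 5 FPKM, where fewer genes were tested, 0 with an estimated correlation, 0 with fry and 0 in the replicate block with fry. That filter ended the calls of circadian clock (adjusted p 0.061), ubiquitin ligase and autophagy (0.109) and endothelial (0.246) genes and left interferon response and satellite cell lists too small to test, and no filter that of satellite cell markers (0.158). With no filter beta-oxidation (0.0312), triglyceride storage (0.00861), PPAR target (0.0264), fibro-adipogenic (0.0226) and tendon (0.0194) lists passed. With array weights 21 lists passed, among them beta-oxidation (0.00595), triglyceride storage (0.0205), PPAR target (0.0138) and Schwann cell (0.0194) lists. Leaving out 1 library gave 11 to 21 lists. Oxidative phosphorylation subunits had a median of 0.01 that did not pass and passed at −0.17 with array weights, −0.16 without K15SKO 3 and 0.18 without K15SKO 2. Their medians against the MyoCre mean were −0.04, −0.30 and 0.40 in K15SKO 1 to 3. The sign thus follows which of these libraries is left out or given less weight. The labels do not say that the replicate numbers pair the samples. Deviations from the group means of libraries with the same number correlated at 0.0, 0.09 and 0.09, and those of other pairs at −0.09 to 0.01. These values cannot settle pairing, since the K15SKO libraries differ widely among themselves. The replicate block gave 3 genes and 14 lists by camera. No count test and no comparison by the authors was run or used here, since the values are not counts. With the depth unknown, values near 0 cannot be told from too few reads.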

Other observations

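Further lists did not pass camera with all 6 libraries, and some passed without 1 of them. Camera adjusted p was 0.059 for fibro-adipogenic progenitor markers (median −0.20), where Gsn stood at 134 ± 37.5 against 259 ± 20.0 FPKM and Pi16 at 4.90 ± 1.36 against 9.38 ± 1.38 FPKM (SD, n = 3 each), and 2 members were lower adjusted over the list alone. This list passed without MyoCre 3 (0.015), K15SKO 1 (0.00408) and K15SKO 2 (0.0162). Tendon markers had a median of 0.65 (0.135, and 0.0273 without K15SKO 2), with Scx at 14, 7.57 and 3.54 FPKM in K15SKO 1 to 3 against 2.80 ± 0.389 FPKM. Schwann cell markers had a median of −0.35 (0.106, and 0.0225 without K15SKO 3 or 0.0425 without MyoCre 3). Smooth muscle and pericyte markers had a median of −0.09 and a mean of 0.01 (0.716), with Acta2 at 17.2 ± 1.32 against 11.3 ± 0.926 FPKM and 1 member higher adjusted over the list alone. Red blood cell markers had a median of −0.22 (0.609), and Hbb-bs ranged from 57.7 to 363 FPKM within MyoCre. Genes of the integrated stress response had a median of −0.07 (0.795), with Chac1, which degrades glutathione, at 46.1 ± 24.5 against 153 ± 32.2 FPKM. The Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d were expressed in all 6 libraries, with Ddx3y between 11.5 and 24.8 FPKM.

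All tests in the paragraphs that follow were chosen after the results were seen. The 6 libraries allow 10 splits into groups of 3, too few for a share under 0.05. The real split gave 6 genes and the highest other 2, with as many in 1 of 10 splits. With genes at 0 in a whole group left out, the real split gave 0 and the highest other 2. For gene lists the real split gave 14 and the highest other 22, with as many in 4 of 10.

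K15SKO 2 held abundant transcripts of liver. Of 40 liver genes 95% were at least 10-fold above the highest of the other 5 libraries, with Alb at 2203, Apoa2 at 930 and Mup3 at 843 FPKM. A few of the 40, such as Trf and Cyp2e1, stood at over 10 FPKM in MyoCre, and their cell source was not tested. The tables argue against a liver sample in place of muscle, since the 10 most abundant MyoCre genes kept a median of 62.9% of their MyoCre mean. They also argue against Klf15 loss as the source of that level. Over 36 of the genes, chosen for being low in MyoCre against K15SKO 2, K15SKO 1 and 3 held a median of 1.09% and 0.184% of it. The MyoCre libraries held 0.054%, 0.013% and 0.004%, values kept low by that choice. Of all 40 genes, 36 in K15SKO 1 and 32 in K15SKO 3 lay above every MyoCre library. Cyp2e1 and Hp lay below every MyoCre library in both. The source of the low levels in K15SKO 1 and 3 was not tested. Liver tissue or RNA in K15SKO 2 is a candidate source of its liver transcripts, and its Klf15, Prodh, Gpt and Errfi1 values may include it. How much liver RNA added to those values was not tested.

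Regeneration and macrophage genes were high in K15SKO 1 and 2 and not in K15SKO 3. A smaller share of muscle fibres, with the other cells in unchanged proportions, would raise the markers of those cells alike. The endothelial medians were −0.67 and −0.43 in K15SKO 1 and 2 where the macrophage medians were 2.19 and 1.33, which argues against that form alone. A smaller share of fibres together with more macrophages stays open. The medians of fast fibre genes other than Pvalb and Myh1 were 62.0%, 65.1% and 110% of the MyoCre mean in K15SKO 1 to 3. Liver RNA does not account for K15SKO 1, whose regeneration median was 1.85 at 1.09% of the liver level of K15SKO 2. The extent of Klf15 loss cannot be told apart from other differences between these samples. The regeneration median of K15SKO 3 minus that of K15SKO 2 was −1.57 log2 units with less Klf15 in K15SKO 3. The Klf15 of K15SKO 2 may include liver RNA, but how much was not tested. Injury or separate handling of these samples was not tested.

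Pvalb, Myh1 and Gm12300 were listed at 0 in a whole group and high in the other. Of the 11 other fast fibre genes, most stood between 54.1% and 91.1% of MyoCre in K15SKO, while Myh2 in MyoCre was at 23.4% of K15SKO. These levels cannot decide whether the zeros were failed estimates, since a failure at a locus says nothing about other genes. A switch of fibre type with genotype would also place Myh1 at 0. Myh1 and the antisense Gm12300 were both at 0 in all K15SKO libraries, but they overlap, so their zeros may be 1 event. Pvalb ran the other way, and the tables argue against more fast fibres as the source of its rise from 0 to 5041 FPKM or more: the medians of the 11 other genes were 62.0%, 65.1% and 110% of the MyoCre mean in K15SKO 1 to 3, and the highest single value was 606%, for Myh2. For Myh1 and Gm12300 failed estimates and a switch of fibre type cannot be told apart. Without counts a failed estimate and an unexpressed gene look alike. For Pvalb the values above argue against a switch to more fast fibres. Fast fibre genes were abundant in MyoCre 1 to 3, with Tnnc2 at 13605, 13099 and 16329 FPKM and Actn3 at 3255, 2925 and 3947 FPKM. These values argue against a lack of fast fibres as the source of the Pvalb zeros. Whether its zeros in MyoCre are failed estimates cannot be told without counts, so its values support no reading as a gene raised by Klf15 loss.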
